A study of Homo sapiens with 32 samples.

How the data were processed

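Cap analysis of gene expression (CAGE) counts the capped 5′ ends of RNAs, so that each tag marks a position where transcription started. The series holds 32 CAGE libraries of human prostate cancer cell lines, and 2 tables of start sites were deposited. The first table holds 14 LNCaP libraries from a time course with the synthetic androgen R1881, at 7 times with 2 replicates each. The second holds 18 libraries, 9 of LNCaP and 9 of BicR cells, with 1 library for each combination of line, treatment and time. Per the labels, total RNA was reverse transcribed, capped molecules were trapped, and the cDNA was read on a HeliScope sequencer. Per the submitters' processing notes the genome build was hg19. The aligner, the cluster caller and any filter on the clusters are not stated.

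Per the file headers, each table gives raw tag counts per site and a normalized value. The deposited tag counts are whole numbers without normalization. The deposited RPM values (reads scaled to a common library total) are the tag counts of a library times 1 factor, which implies a total larger than the table's own sum, and which tags make up that total is not stated. The tags in the tables were 75.57 to 90.14% of that total. The R1881 table lists 19534 clusters with a median width of 139 bp, and the LNCaP and BicR table lists 13294 single positions, each of which reached at least 10 RPM in 1 or more libraries. The tables shared 8549 site names. All columns of per-sample values were matched to a sample. The tables pair no site with a gene name, and 0 of their names matched the gene table that came with the data, which is for another build. Sites are therefore given by hg19 chromosome, start, end and strand, counted from 1. Sums per gene, the named androgen-regulated genes and the gene lists fixed beforehand could not be computed.

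Tests were run on the deposited counts in R 4.3.3 with edgeR 4.0.16, using TMM normalization and the quasi-likelihood F test. Benjamini-Hochberg adjustment ran over all sites tested, with a threshold of 0.05 on the adjusted p. The filter filterByExpr with a minimum count of 10 kept 15999 sites of the R1881 table and 13294 of the other. The time course was fitted with a coefficient per time over the 14 libraries. In the other table, with 1 library per condition, each line and treatment had a coefficient and each line a term for 24 h against 6 h. The 6 h and 24 h libraries thus stood in for replicates, and the residual was the deviation of treatment effects between these times. The comparison of late with early times used 48 h and 72 h against 3 h and 6 h, a fit of 8 libraries over 11193 sites. All adjusted p-values below come from edgeR's quasi-likelihood test unless another test is named, and SE is the standard error of the log2 fold change, computed as its size over the square root of F.

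Unequal change among neighbouring start sites was tested with edgeR's diffSpliceDGE and the Simes method, on the mean of 18 h, 48 h and 72 h against 0 h. Because the tables name no genes, sites on the same strand were joined into a neighbourhood when the next site lay within 10000 bp, a choice made after the tables had been read. Sets of sites chosen in 1 table were tested in the other with limma 3.58.1 (camera) at a preset correlation of 0.01 between sites, and again with the correlation estimated from the libraries. The sets were to be the sites called at 6 h of R1881. No site was called there, so the sets called at 48 h were used, an alternative fixed beforehand. Confidence intervals of tag ratios are exact binomial intervals at 95%. They and the limit that 3 tags set for a site with 0 tags cover counting error only. That limit was averaged over the libraries of a group, at 3 tags per library.

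The rule for named sites asked for a mean of at least 10 RPM over the libraries compared. It took the 6 largest rises and falls at 48 h of R1881 with replicates that did not overlap those at 0 h. It took 4 each way for late against early times, 6 each way for DHT, 4 each way for bicalutamide, and 10 each way between the lines. Those from the second table had to change the same way at 6 h and 24 h. Since the tables pair no names with the sites, at most 2 rises and 2 falls per comparison are printed. These are the largest, and the one with the most tags in the higher group, a choice made after the values were seen. Single sites were followed under the alternatives only for the 2 largest rises and 2 largest falls of each comparison. Other printed sites were not followed.

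Replicates of the time course share a number across times. Deviations of same-numbered libraries from their time's mean correlated at 0.14 to 0.602 (median 0.353, 12348 sites) for 21 of 21 pairs of times, so the numbers pair the libraries. The labels do not say what the numbers stand for. The replicate number as a block was fixed beforehand as an alternative, and its counts stand beside the main ones. With the block, 2633 sites differed between the replicate numbers. The biological coefficient of variation was 0.423 without the block, 0.282 with it, and 0.122 in the LNCaP and BicR fit. Nothing in the labels says that replicates came from separate cultures. If they did not, the p-values measure only a spread between libraries that may be technical. Replicates differed by more than sampling noise at each time (chi-square per degree of freedom 6.49 to 20.7), so none was counted as a repeat deposit.

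The fits at 6 h and 48 h, of DHT in BicR, between the lines, of late against early times and of neighbourhoods were run on simulated data drawn from the real means, with 50 sites changed by each of 4 sizes of fold. The other comparisons were not simulated at the level of sites. Among 15999 sites simulated as in the 48 h comparison, 0% of 2-fold, 10% of 4-fold, 68% of 16-fold and 84% of 64-fold changes were recovered. With the replicate block these were 14%, 52%, 86% and 94%. At 6 h they were 0%, 8%, 62% and 70%. For DHT in BicR (13294 sites) 70% of 2-fold and 92% of 4-fold changes were recovered, for BicR against LNCaP 72% and 98%, for late against early times (11193 sites) 6% and 56%, and for neighbourhoods (2037) 4% and 32%. Unchanged sites made up 11% of the calls at 48 h, 12.1% with the block and 6.67% at 6 h. The share was 5.73% for DHT in BicR, 2.63% between the lines, 5.8% for late against early times and 9.68% of the neighbourhoods called. Most shares lay above the nominal 5%, but each came from 1 simulated draw, so those near 5% cannot be told from it. The simulated means held no replicate effect, so recovery and shares may differ in the real, paired libraries. Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors (RLE), no filter, a log2 fold threshold of 1, the replicate block, fits of fewer libraries, a fit with no time term and leaving out each library. The tests used counts without a pseudocount. Log2 levels took a prior count of 2 for changes in single DHT libraries, medians of sets by time and chromosome medians of single libraries. Positions of libraries on the scale between the lines used RPM, without a log or a prior count. Correlations between libraries took a prior count of 3 unless another is named. Prior counts of 0.5 and 8 were tried after the data were seen.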

Results

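CAGE tags were counted at start sites in LNCaP, an androgen-responsive human prostate cancer cell line, and in BicR, a second prostate cancer line whose name the labels do not spell out. The study asked where in the genome androgens change the start of transcription. Cells were kept in medium with hormone-depleted serum before treatment. In the first experiment LNCaP cells received R1881, a synthetic androgen, and were sampled at 0, 3, 6, 12, 18, 48 and 72 h, with 2 libraries per time. The sample characteristics give 1 nM R1881, whereas the shared treatment protocol states 10 nM for 24 h, so the dose is uncertain. In the second experiment both lines received ethanol (the vehicle), 10 nM dihydrotestosterone (DHT, a natural androgen), 1 µM bicalutamide (an androgen receptor antagonist), or DHT with bicalutamide. Each of these 8 combinations gave 1 library at 6 h and 1 at 24 h, and each line gave 1 library before treatment.

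Depth differed between the experiments. Time course libraries held 128463 to 3837493 tags, and replicate 1 was the shallower at every time. Its libraries at 6 h and 18 h held 140956 and 128463 tags, where 3 tags correspond to 17.1 and 19.45 RPM. The libraries of the second experiment held 4139807 to 7753336 tags, with 3 tags at 0.326 to 0.601 RPM. Log2 levels of the replicates correlated across sites at 0.902 for 0 h, 0.895 for 48 h and 0.906 for 72 h, and at 0.636 for 6 h and 0.65 for 18 h.

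Start-site levels changed over days of R1881. The time course has no vehicle library after 0 h, so R1881 cannot be told apart from time in culture. After 48 h the site at chromosome 7, 87936131 to 87936408 on the minus strand, stood at 279 ± 104 RPM (SD, n = 2) against 0.138 ± 0.195 at 0 h, a log2 change of 10.04 (SE 1.03, adjusted p = 0.000481). With 1 tag at 0 h, its pooled tag ratio was 1110-fold with a counting interval of 200 to 44100. The site at chromosome 11, 134094966 to 134095596 on the minus strand, rose from 10.1 ± 1.40 to 3945 ± 2570 RPM (log2 8.67, SE 1.09, adjusted p = 0.00168). On chromosome 10, 55036028 to 55036052 on the minus strand, 101.1 ± 78.6 RPM at 0 h fell to 0 tags, at least 37.5-fold lower (adjusted p = 0.0106). That site no longer passed without replicate 1 of 0 h (adjusted p = 0.0549) or replicate 1 or 2 of 48 h (0.0578 or 0.157). On chromosome 1, 222867611 to 222868200 on the minus strand, the level fell from 663 ± 125 to 5.44 ± 3.12 RPM (log2 -7.10, SE 0.735, adjusted p = 0.000481). Among the other 4 named rises, a pair with 0 tags at 0 h rose at least 21.6-fold and 12.6-fold, and the others had log2 changes of 7.54 and 7.39, the last with 1 tag at 0 h and a pooled ratio of 200-fold (35.5 to 7950). Among the other 4 named falls, a pair with 0 tags at 48 h fell at least 14.2-fold and 8.62-fold, and a pair with 1 tag at 48 h had pooled ratios of 240-fold (42.6 to 9490) and 188-fold (33.3 to 7450).

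**Figure D1:**
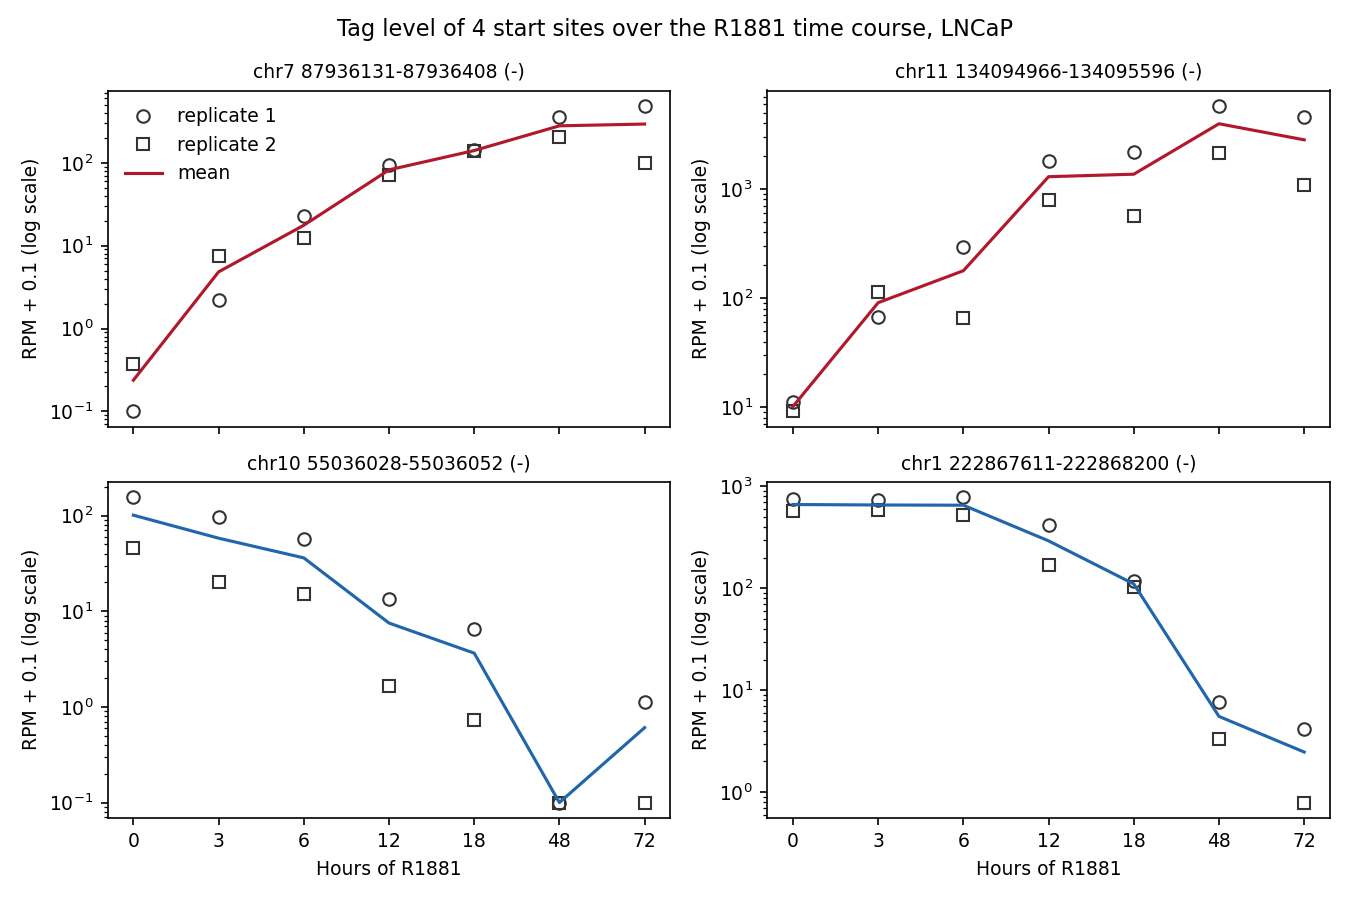
Level in RPM plus 0.1 (log axis) against hours of R1881 for the 4 sites described at 48 h, with open symbols for the 2 replicates and lines for their mean. The chromosome 11 site goes from 10.1 RPM at 0 h to 3945 at 48 h, and the chromosome 1 site from 663 to 5.44.

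Of 15999 sites tested, 223 rose and 79 fell at 48 h, and 242 rose and 158 fell at 72 h. Of the rising sites 178 were shared by both times, and of the falling sites 70. Independent lists would share 3.37 and 0.78. Simulated unchanged groups against the same 0 h libraries shared 0 in 20 draws, a value that leaves out any effect. These draws took their means from the 0 h libraries themselves, so they cannot show how much those libraries add to the sharing. Part of the excess may come from the shared 0 h libraries. With the replicate number as a block, 793 sites rose and 573 fell at 48 h, and 1005 rose and 942 fell at 72 h. The counts rest on both replicates. At 48 h, 24 or 27 sites passed without 0 h replicate 1 or 2, and 70 or 64 without 48 h replicate 1 or 2. At 72 h the same omissions gave 83 or 40 and 159 or 76 sites. Without the 6 h and 18 h libraries of replicate 2, which stand apart, 639 sites passed at 48 h and 960 at 72 h, and without the 4 shallowest libraries 505 and 817.

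**Figure D2:**
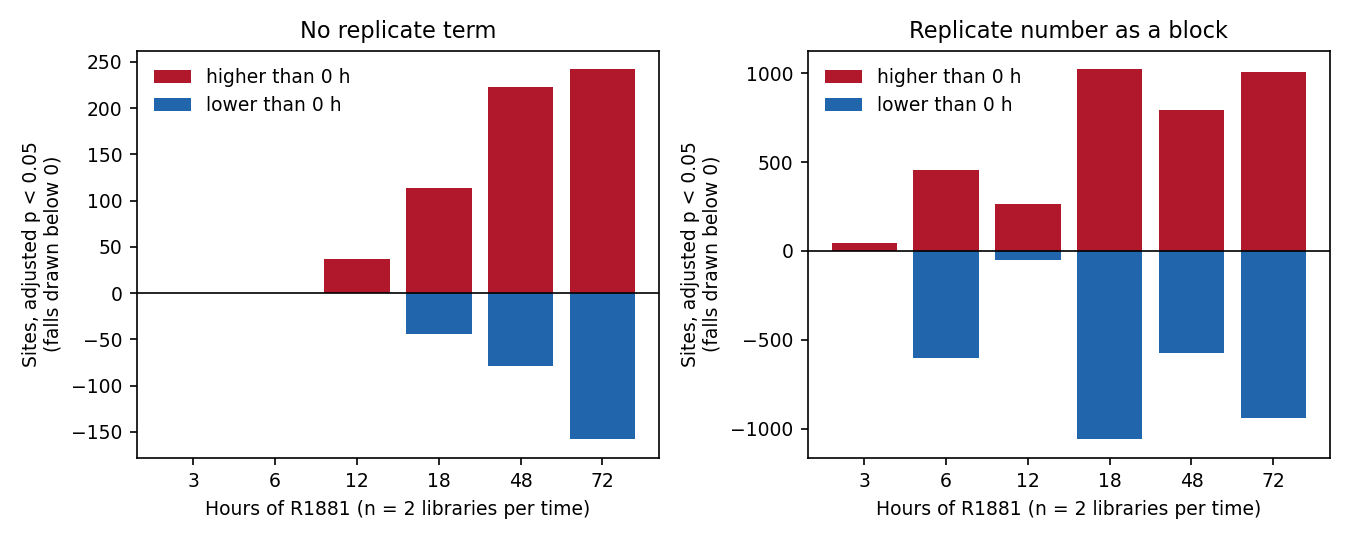
Number of start sites with an adjusted p under 0.05 against 0 h (edgeR) at each hour of R1881, with rises above and falls below 0, without a replicate term (left) and with the replicate number as a block (right). Without the block the counts go from 0 at 3 h to 242 rises and 158 falls at 72 h, and with it from 46 rises at 3 h to 1005 rises and 942 falls. With the block the course is not steady: 1058 sites passed at 6 h, 316 at 12 h, 2082 at 18 h and 1366 at 48 h. The 6 h and 18 h libraries of replicate 2, which stand apart, enter these counts.

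The sites called at 48 h were followed over the other times. The 223 rising sites had a median log2 change of 1.27 at 3 h (207 higher), 1.52 at 6 h (194 higher), 2.49 at 12 h, 2.84 at 18 h, 3.64 at 48 h and 3.57 at 72 h. With the 20 sites that had 0 tags at 0 h or 48 h at their bound, the median at 48 h was 3.30. The 79 falling sites had medians of -0.46 at 3 h (69 lower), -1.24 at 6 h, -1.90 at 12 h, -2.70 at 18 h, -3.84 at 48 h and -3.91 at 72 h, and -3.35 at 48 h with the 10 sites that had 0 tags in a group at their bound. These sites were chosen for their difference from the same 0 h libraries that each time was compared with, so part of the early medians is given by that choice.

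At 12 h, 37 sites rose and 0 fell (996 at an unadjusted p under 0.05), and at 18 h 114 rose and 44 fell. The chromosome 11 site stood at 1292 ± 706 RPM at 12 h (log2 7.0, SE 1.02, adjusted p = 0.012), and the chromosome 7 site at 82.1 ± 15.5 (log2 8.21, SE 1.02, adjusted p = 0.00462). No site passed at 3 h or 6 h by edgeR. At 3 h 269 sites had an unadjusted p under 0.05 and DESeq2 called 5, and at 6 h these counts were 2449 and 75. With the block, 46 sites rose at 3 h, 454 rose and 604 fell at 6 h, 263 rose and 53 fell at 12 h, and 1022 rose and 1060 fell at 18 h. At 12 h 0 sites passed without either 0 h library and 9 or 11 without 12 h replicate 1 or 2, and at 18 h 0 without either 0 h library, 376 without 18 h replicate 1 and 21 without 18 h replicate 2. At 6 h 297 sites passed without 6 h replicate 1. The 6 h and 18 h libraries of replicate 2, which stand apart, enter all of these counts, and without them 0 sites passed at 6 h, 97 at 12 h and 39 at 18 h. A joint test of the 6 times called 256 sites, and 2892 with the block.

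Late times differed from early times directly. In the 4 libraries of 48 h and 72 h against the 4 of 3 h and 6 h, 365 sites were higher and 342 lower of 11193 tested. On chromosome 2, 238395773 to 238395861 on the minus strand, 0 tags at the early times became 27.2 ± 12.5 RPM (SD, n = 4), at least 4.14-fold higher (adjusted p = 0.00121). On chromosome 19, 54371084 to 54371184 on the plus strand, 13.5 ± 11 RPM became 483 ± 208 (log2 5.48, SE 0.614, adjusted p = 0.000464). The chromosome 1 site that fell at 48 h went from 655 ± 124 to 3.90 ± 2.87 RPM (log2 -7.81, SE 0.565, adjusted p = 1.78e-05). On chromosome 7, 50547651 to 50547760 on the minus strand, 47.6 ± 26.4 RPM became 0.382 ± 0.764, a pooled ratio of 349-fold for 1 late tag with a counting interval of 61.8 to 13900 (adjusted p = 0.000367). With the replicate block 543 sites were higher and 591 lower. Without 1 library the total of 707 became 460 (72 h replicate 1), 371 (3 h replicate 2) or 332 (72 h replicate 2).

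Neighbouring start sites on the same strand did not always change alike. Of 2037 neighbourhoods, 40 showed unequal change between 0 h and the mean of 18, 48 and 72 h. On chromosome 19 the site at 38866598 to 38866789 on the plus strand went from 0.396 to 41.5 ± 24.2 RPM (SD, n = 6; log2 7.10, SE 0.925), while a site 1266 bp away went from 330 to 912 RPM (log2 1.502, SE 0.337; neighbourhood adjusted p = 0.000629). For the first, 1 tag at 0 h gave a pooled ratio of 214-fold with a counting interval of 38.2 to 8460. On chromosome 1 the site at 222884778 to 222885182 on the plus strand fell from 59.3 ± 19.1 to 4.52 ± 2.58 RPM (log2 -3.89, SE 0.376), while sites 1077 and 1889 bp away had log2 changes of -0.46 and 0.86 that did not pass (neighbourhood adjusted p = 3.15e-05). The remaining 3 of the 5 leading neighbourhoods lay on chromosomes 11, 8 and 19. The replicate block gave 109 neighbourhoods, and links within 1 kb or 50 kb gave 4 or 145. Without 0 h replicate 1 or 2 the count was 13 or 4, without 48 h or 72 h replicate 1 it was 26 each, and without 18 h or 72 h replicate 2 it was 13 or 20.

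DHT changed more sites in BicR than passed in LNCaP. In LNCaP 14 sites rose and 1 fell of 13294. The site at chromosome 8, 80993064 on the minus strand, stood at 41.1 ± 0.317 RPM over 6 h and 24 h (SD, n = 2) against 4.30 ± 1.26 with ethanol (log2 3.33, SE 0.435, adjusted p = 0.0164). At chromosome 19, 51376694 on the plus strand, the level was 313 ± 9.55 against 36.4 ± 5.84 RPM (log2 3.19, SE 0.376, adjusted p = 0.0128). At chromosome 17, 41152046 on the plus strand, it was 7.51 ± 1.10 against 20.4 ± 2.68 RPM (log2 -1.39, SE 0.226, adjusted p = 0.0409). With bicalutamide alone that position had a log2 change of -1.39 (SE 0.226, adjusted p = 0.116) against the same ethanol libraries. The chromosome 8 and 17 sites no longer passed when any 1 of the 4 libraries compared was left out (adjusted p = 0.0659 to 0.397 and 0.143 to 0.526), nor the chromosome 19 site in 3 of these 4 omissions (0.143 to 0.397). In LNCaP 2 sites passed without DHT 6 h, 1 without DHT 24 h or ethanol 6 h, and 0 without ethanol 24 h. DESeq2 called 51 sites.

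In BicR 291 sites rose and 152 fell with DHT, and the 443 had the same direction at 6 h and 24 h. At chromosome 6, 41715134 on the minus strand, the level was 28.1 ± 14.5 against 0.329 ± 0.0863 RPM (log2 6.28, SE 0.591, adjusted p = 0.000372). At chromosome 11, 134095354 on the minus strand, within the chromosome 11 cluster described at 48 h of R1881, it was 117 ± 43.1 against 4.89 ± 1.22 RPM (log2 4.50, SE 0.558, adjusted p = 0.00155). Both leading falls lay on chromosome 21, minus strand. Position 30305115 had 8.11 ± 1.06 against 70.8 ± 24.2 RPM (log2 -3.17, SE 0.54, adjusted p = 0.00667), and 30308522 had 14.5 ± 0.14 against 107 ± 41.1 RPM (log2 -2.90, SE 0.467, adjusted p = 0.00473). Neither passed without DHT 6 h (adjusted p = 0.0756 and 0.0603) or DHT 24 h (0.0988 and 0.0799), nor the first without ethanol 24 h (0.0632). The difference between the lines in the response to DHT passed at 0 sites by edgeR, with 751 at an unadjusted p under 0.05 and 3 called by DESeq2. In BicR 175 sites passed without DHT 6 h, 148 without DHT 24 h and 260 without ethanol 24 h. With no time term 186 passed.

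Bicalutamide alone changed sites in BicR, where it acted on 21 upward and 4 downward. At chromosome 2, 234862316 on the plus strand, the level was 20.3 ± 0.0337 against 1.84 ± 0.894 RPM (log2 3.52, SE 0.476, adjusted p = 0.0212). At chromosome 21, 42880084 on the minus strand, it was 82.9 ± 31.3 against 15.1 ± 0.522 RPM (log2 2.52, SE 0.417, adjusted p = 0.0447). At chromosome 2, 172291281 on the minus strand, it was 9.35 ± 0.433 against 21.7 ± 2.88 RPM (log2 -1.16, SE 0.201, adjusted p = 0.046), and at chromosome 3, 3841114 on the plus strand, 49.7 ± 17 against 100.6 ± 15.5 RPM (log2 -0.99, SE 0.132, adjusted p = 0.0212). Position 234862316 no longer passed without 1 library in 3 omissions (adjusted p = 0.0579 to 0.37), nor 172291281 in 4 (0.0905 to 0.575). In LNCaP 0 sites passed by edgeR, with 252 at an unadjusted p under 0.05, a smallest adjusted p of 0.0502 and 2 called by DESeq2. The difference between the lines passed at 0 sites (417 at an unadjusted p under 0.05, 10 by DESeq2). In BicR 0 sites passed without ethanol 6 h or with no time term, 1 without bicalutamide 6 h, 3 without ethanol 24 h, and 69 without bicalutamide 24 h.

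Bicalutamide added to DHT was compared with DHT alone, which asks whether the antagonist opposes the androgen. In LNCaP 0 sites passed by edgeR, with 238 at an unadjusted p under 0.05 and 0 by DESeq2. In BicR 17 sites rose and 0 fell, with 1157 at an unadjusted p under 0.05 and 9 by DESeq2. Of the 17, 16 were among 224 sites near 0 in 15 of the 18 libraries, and 1 had the same direction at 6 h and 24 h. That site, at chromosome 4, 57976550 on the minus strand, had 61.7 ± 87.1 against 0.29 ± 0.411 RPM (log2 7.68, SE 0.867, adjusted p = 0.00498). These tags lay in the BicR library of DHT with bicalutamide at 6 h, which stands apart from the other BicR libraries. Without it, or without DHT 6 h, 0 sites passed, and without the 24 h library of the combination 926 passed. Against ethanol, 255 sites were higher and 96 lower with DHT and bicalutamide in BicR, and 1 was higher in LNCaP, a comparison added after the data were seen. Without the BicR library that stands apart 239 were higher and 193 lower in BicR, without the near-empty sites 172 and 82, and without the 3 libraries that hold tags at those sites 130 and 70, with 0 in LNCaP.

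With ethanol the lines differed at 1459 sites, 678 higher and 781 lower in BicR. At chromosome 10, 30024275 on the minus strand, BicR had 81.0 ± 9.67 RPM and LNCaP 0 tags, at least 197-fold higher (adjusted p = 5.7e-05, and 0.0723 without LNCaP ethanol 6 h). At chromosome 19, 51376694 on the plus strand, which rose with DHT in LNCaP, BicR had 145 ± 10.5 against 36.4 ± 5.84 RPM (log2 2.09, SE 0.367, adjusted p = 0.00544). At chromosome 11, 4665211 on the plus strand, BicR had 1 tag (0.0669 RPM) against 32.03 ± 10.3 RPM, a pooled ratio of 495-fold with a counting interval of 88.4 to 19600 (adjusted p = 0.000138, and 0.258 without BicR ethanol 6 h). At chromosome 3, 165555207 on the minus strand, it was 21.1 ± 7.06 against 624 ± 174 RPM (log2 -4.74, SE 0.903, adjusted p = 0.00798). Sites on chromosome 15 were lower in BicR as a group, with a median log2 change of -0.36 and 311 of 374 lower. Chromosome 1 had a median of -0.135 with 856 of 1308 lower. Sites on chromosomes 2 and 9 were higher, with medians of 0.25 for both and 659 of 841 and 432 of 550 higher. Without the 6 h or 24 h ethanol library of LNCaP 363 or 408 sites passed, and without the 6 h library of BicR 373. The mean over the 4 treatments, with more libraries, called 6202.

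**Figure D3:**
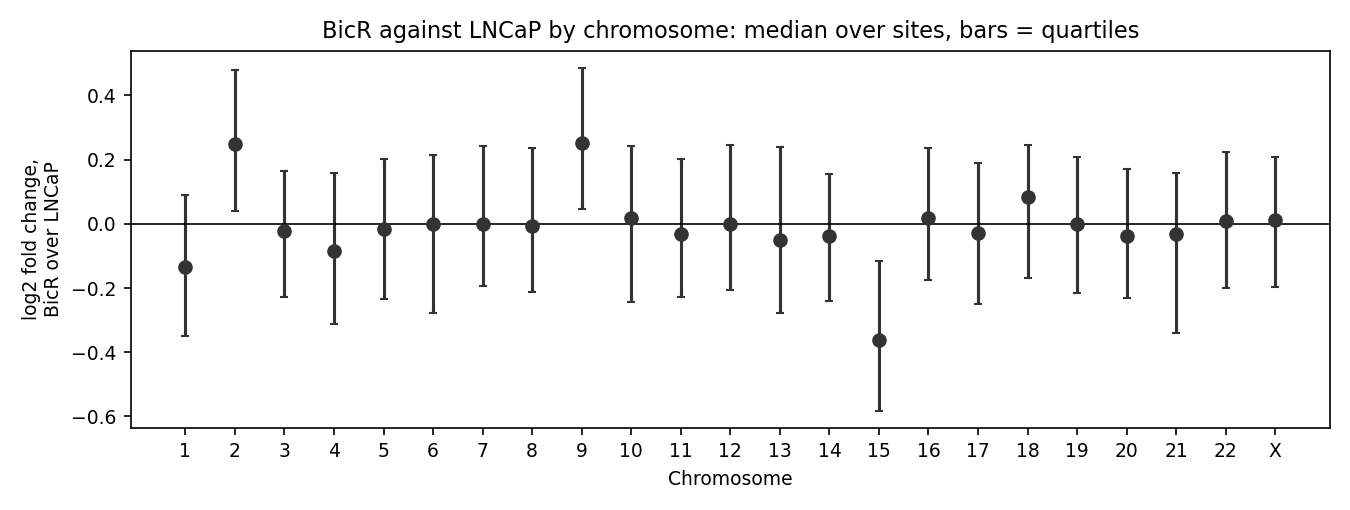
Median log2 change of BicR over LNCaP with ethanol for the tested sites of each chromosome, with bars from the lower to the upper quartile. Chromosome 15 lies at -0.36 and chromosomes 2 and 9 at 0.25, while chromosome 7 lies near 0.

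Sites that responded to R1881 were then followed in the second experiment. Of the sites called at 48 h, 102 rising and 56 falling ones were in its table. The rising set was higher with DHT in LNCaP by a median log2 of 0.68 (98 of 102 sites, camera adjusted p = 2.18e-38, and adjusted p = 0.0039 with an estimated correlation) and in BicR by 1.04 (83 of 102, adjusted p = 4.77e-42, and adjusted p = 0.0039). Adjusted over the list alone, 37 of its sites passed as higher in LNCaP, and 66 as higher and 1 as lower in BicR, against 4 and 51, all higher, over all sites. For the larger set of 372 rising sites from the fit with the replicate block, the medians were 0.34 in LNCaP and 0.43 in BicR. The falling set had a median of -0.37 in LNCaP (48 of 56 lower, camera adjusted p = 7.36e-08, but adjusted p = 0.22 with an estimated correlation). In BicR its median was -0.999 (51 of 56 lower, camera adjusted p = 4.28e-21, but adjusted p = 0.0639 with an estimated correlation). For the larger set of 386 falling sites from the blocked fit, the medians were -0.174 in LNCaP and -0.36 in BicR.

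With bicalutamide alone the rising set did not move in LNCaP beyond other sites (median 0.03, 58 of 102 higher, adjusted p = 0.454). In BicR it was higher by 0.67 (89 of 102, adjusted p = 9.3e-34, and adjusted p = 0.0039 with an estimated correlation). The difference between the lines passed for bicalutamide (median 0.60, 87 of 102 higher, adjusted p = 2.16e-22, and adjusted p = 0.00563) and for DHT (0.57, 74 of 102 higher, adjusted p = 1.25e-09, and adjusted p = 0.0399). Both differences used the same ethanol libraries, so a deviating ethanol library could shift both. The LNCaP library with bicalutamide at 6 h holds tags at the near-empty sites. Without the 3 such libraries the bicalutamide median was 0.695, resting on 24 h alone in LNCaP. With DHT the medians in BicR and LNCaP were 1.02 and 0.45 at 6 h and 0.91 and 0.79 at 24 h, from single libraries. For the larger sets from the fit with the replicate block, bicalutamide in BicR had a median of 0.27, the bicalutamide difference 0.285 (adjusted p = 0.00979 with an estimated correlation), and the DHT difference 0.16 (adjusted p = 0.11). The falling set in BicR had a median of -0.50 with bicalutamide (camera adjusted p = 6.76e-17, but adjusted p = 0.0877 with an estimated correlation). The falling set from the blocked fit had a median of -0.199 there.

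Adding bicalutamide to DHT lowered the rising set in LNCaP by a median of -0.23 against DHT (86 of 102 lower, adjusted p = 5.52e-10, and adjusted p = 0.0366 with an estimated correlation, 0.0751 with a median of -0.11 for the sets from the blocked fit). Against ethanol its medians with DHT and with the combination were 0.45 and 0.40 at 6 h and 0.79 and 0.37 at 24 h. In the fit over both times the set stayed higher than with ethanol by 0.54 with the combination (91 of 102, adjusted p = 4.81e-24, and adjusted p = 0.00552). In BicR the combination differed little from DHT (median -0.08, 59 of 102 lower, adjusted p = 0.127), and against ethanol it stood at 1.13 (96 of 102 higher, adjusted p = 1.01e-47, and adjusted p = 0.0039). For the sets from the blocked fit these medians against ethanol were 0.26 in LNCaP and 0.51 in BicR. For the 102 sites they were 0.409 in LNCaP and 0.958 in BicR without the 3 libraries that hold tags at the near-empty sites. Those fits leave the combination at 24 h only. The falling set of BicR had a median of 0.27 against DHT (adjusted p = 0.00143, but adjusted p = 0.458 with an estimated correlation), and -0.17 without the 3 libraries that hold tags at the near-empty sites.

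**Figure D4:**
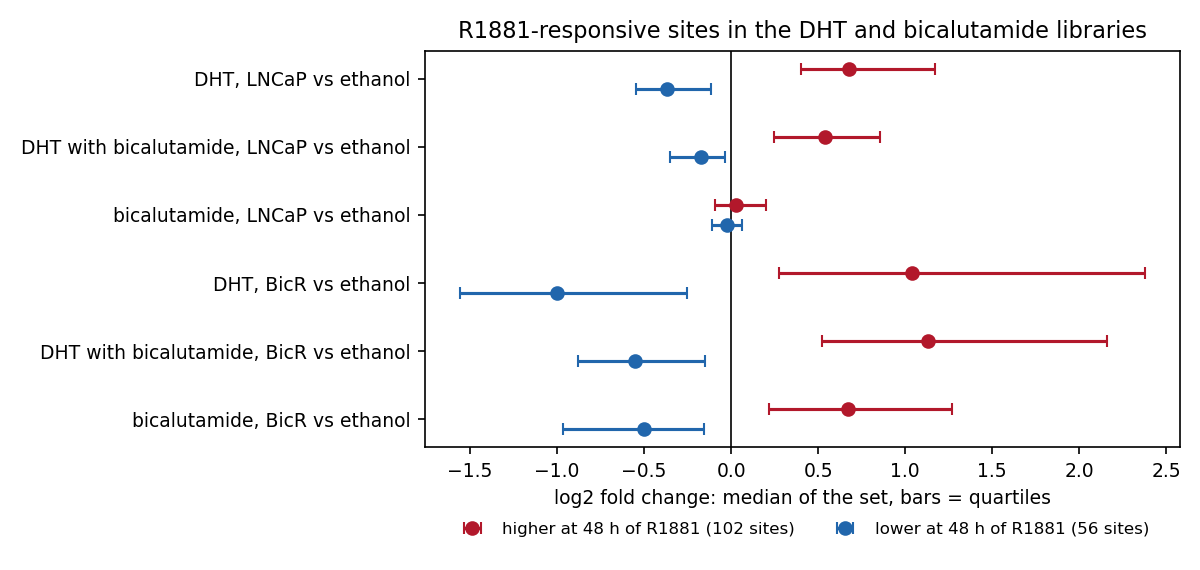
Median log2 change against ethanol, with quartile bars, in each treatment and line of the second experiment, for the 102 sites that rose (red) and the 56 that fell (blue) at 48 h of R1881. The rising set lies at 0.68 with DHT in LNCaP, at 0.03 with bicalutamide in LNCaP and at 0.67 with bicalutamide in BicR.

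Sites called with DHT were followed in the R1881 time course, a comparison added after the data were seen. The 214 sites that rose with DHT in BicR and were tested there stood higher at 3 h of R1881 by a median log2 of 0.78 (196 of 214, camera adjusted p = 2.08e-53, and adjusted p = 0.000555 with an estimated correlation), and by 1.63 at 48 h (200 of 214, adjusted p = 5.93e-52, and adjusted p = 0.000376). The 100 sites that fell with DHT in BicR had medians of -0.36 at 3 h (adjusted p = 2.99e-08, and adjusted p = 0.0181) and -1.39 at 48 h (adjusted p = 1.16e-26, and adjusted p = 0.000376). The 11 sites that rose with DHT in LNCaP had a median of 2.12 at 3 h (11 of 11 higher, adjusted p = 1.03e-25, and adjusted p = 0.00081).

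Both androgens were also set side by side in LNCaP, with 10 nM DHT and an uncertain dose of R1881. Across 8453 sites, the log2 change after 6 h of R1881 and that after 6 h of DHT in single libraries correlated at Pearson's r of 0.324 and Spearman's rho of 0.299. Sites are not independent replicates, and no p-value was computed. Of the 158 sites called at 48 h of R1881, 110 had the same sign in both. For 48 h of R1881 against 24 h of DHT r was 0.484 (rho 0.299) and the same sign was found at 142 of 158, and for 6 h of R1881 against 24 h of DHT r was 0.122 (rho 0.0234).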

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

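All tests of the 3 patterns weighed below, and the limit on the splits counted, were chosen only after the results were seen. No group holds 4 or more libraries, so a single library could not be tested as far from the rest of its group. Results were picked out here because a tested difference between groups passed. The sites that rose at 48 h of R1881 responded more in BicR than in LNCaP, by a median log2 difference of 0.567 with DHT (camera adjusted p = 0.0399 with an estimated correlation) and of 0.599 with bicalutamide (adjusted p = 0.00563). Both differences used the same ethanol libraries of each line, so they are not separate evidence. For sets from the fit with the replicate block the DHT difference was lost (median 0.158, adjusted p = 0.11 with an estimated correlation), and 0 single sites passed for either. By time, the DHT medians in BicR and LNCaP were 1.02 and 0.447 at 6 h and 0.91 and 0.786 at 24 h. The sites that fell differed by -0.663 with DHT (camera adjusted p = 4.36e-11 at the preset correlation, but adjusted p = 0.14 with an estimated correlation). With bicalutamide they differed by -0.501 (camera adjusted p = 2.16e-12, but adjusted p = 0.12 with an estimated correlation). For falling sites from the blocked fit these differences were -0.227 and -0.16. Late times of R1881 differed from early times at 707 sites, and the replicate numbers pair the libraries. Of 18 splits of these 8 libraries, 4 against 4, with 2 of each replicate number on each side, the real one gave 707 and the highest other 0, and 18 splits are too few for a share under 0.05. The 17 splits that part the numbers unevenly gave at most 0.

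The BicR library of DHT with bicalutamide at 6 h stands apart, and tags from LNCaP cells in it are 1 explanation. On a scale from BicR at 0% to LNCaP at 100%, it lay at 37.2% over 137 sites that are lower in BicR, where the other 8 BicR libraries reached at most 2.61%, and at 57.8% against at most 13.5% over 28 sites that are higher in BicR. A source other than either line is another: 224 sites near 0 in 15 libraries (at most 28.9 RPM in sum) summed to 8252 RPM in it, 666.5 RPM in LNCaP with bicalutamide at 6 h and 189.2 RPM in LNCaP with DHT and bicalutamide at 6 h, and their levels in the first pair of these correlated at a Spearman's rho of 0.665. A response to the treatment could not be told apart, since these sites summed to 7.018 RPM at 24 h, and a response may be short-lived. The 224 sites were picked for a low mean in the 15 libraries, and each listed site reached at least 10 RPM in some library. High sums outside the 15 are thus partly given by that choice. Tags from another source could also shift the positions between the lines, so the tests cannot tell the kinds of foreign tags apart. The BicR comparison of DHT with and without bicalutamide may reflect foreign tags. Of its 17 called sites, 16 were among the 224.

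At 190 sites, the 6 h and 18 h libraries of replicate 2 held 3011 tags against 194364 at 3, 12, 48 and 72 h, a pooled log2 ratio of -3.91. These sites were picked for a mean log2 level at 6 h and 18 h more than 3 below that of the other replicate 2 times named. Their low ratio in replicate 2 is therefore given by the choice. An R1881 response at 6 h and 18 h would lower them in both replicates, and the ratio was -0.317 in replicate 1, from 4964 tags. Sampling of few tags would not carry over between libraries, and 300 sites chosen at 6 h had a ratio of -3.19 at 18 h. At a prior count of 2 the 6 h and 18 h libraries of replicate 2 correlated at 0.947 with each other and at most at 0.857 with any other. At a prior count of 3 these values were 0.951 and 0.866. A shared library batch could give this, but the labels name no batch and the test cannot tell. Counts at 6 h and 18 h may depend on these libraries. Leaving them out cannot settle it, since only replicate 1 then remains at these times. The main count at 6 h was also 0 with them.

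Sites on chromosome 15 were lower in BicR than in LNCaP with a median log2 change of -0.36. Noise of low-level sites would spare the sites with the highest levels, and the median was -0.27 among the 87 sites in the highest 25% of levels. A few co-regulated stretches would leave most windows near 0, and 7 of 7 windows of 10 Mb had medians below -0.1, from -0.386 to -0.248. Fewer copies of the chromosome in BicR could not be told apart from other differences between the lines: 9 of 9 BicR libraries lay below all LNCaP libraries, which restates the pattern, and 9 of 9 also lay outside the LNCaP range on chromosomes 1, 2 and 9. DNA was not measured.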

How the results depend on the processing

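Fits without chosen libraries or near-empty sites, link distances of 1 and 50 kb, sets from the blocked fit and other prior counts were chosen after seeing the data. The replicate block moved the counts at 3, 6, 12, 18, 48 and 72 h from 0, 0, 37, 158, 302 and 400 to 46, 1058, 316, 2082, 1366 and 1947, at any time from 256 to 2892, for late against early times from 707 to 1134, and for neighbourhoods from 40 to 109. Sets chosen in that fit lost the DHT difference between lines (adjusted p = 0.11 with an estimated correlation), bicalutamide on DHT for rising sites in LNCaP (0.0751, likewise) and for falling sites in BicR (0.952), and the falling sites between lines (0.0887 with a median of 0.112, against 0.00157 with -0.495, itself adjusted p = 0.458 with an estimated correlation). The block changed no other call. DESeq2 gave 5, 75, 96 and 485 sites at 3, 6, 12 and 18 h and 671 at any time, 51 for DHT in LNCaP, 3 for DHT by line, 2, 68 and 10 for bicalutamide in LNCaP, in BicR and by line, 9 for bicalutamide on DHT in BicR and 829 between the lines. RLE factors gave 22 sites at 6 h and 1 for bicalutamide in LNCaP. No filter gave 18 at 6 h and 241 at 18 h. Fits of only the 4 libraries compared gave 19, 6, 584 and 744 at 12, 18, 48 and 72 h. A log2 fold of at least 1 left 274 sites for DHT in BicR and 509 between the lines. With no time term these were 186 and 451, with 7 for DHT in LNCaP and 0 for bicalutamide in BicR, alone or on DHT. The mean over the 4 treatments gave 6202 between the lines.

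Neighbourhoods numbered 83 with an F test, 19 with only sites of at least 5 per cent, and 4 or 145 with links of 1 or 50 kb. The correlation of R1881 with DHT at 6 h, 0.324, was 0.122 with DHT at 24 h and 0.295 with R1881 at 18 h. The 6 h sets held 0 sites and gave 0 calls, and over the 9 comparisons fixed beforehand, without DHT with bicalutamide against ethanol, the 48 h sets gave 14, or 6 with an estimated correlation, and from the blocked fit 12 or 4. Without the 6 h and 18 h libraries of replicate 2, 12, 18, 48 and 72 h gave 97, 39, 639 and 960. Without the 4 shallowest libraries, 3, 6, 18, 48 and 72 h gave 1, 1311, 1398, 505 and 817, and any time 1091, with 6 h and 18 h left to the replicate 2 libraries that stand apart. Without the 3 libraries with tags at the near-empty sites, bicalutamide in BicR gave 43 sites and bicalutamide on DHT in BicR 0, as it did without those sites, and DHT with bicalutamide against ethanol gave 200 in BicR (351 with all) and 0 in LNCaP (1 with all). Where a fit used fewer libraries or sites this is part of its construction, and otherwise the cause was not tested.

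Leaving out 1 library at a time gave 0 to 297 sites at 6 h, 0 to 11 at 12 h, 0 to 376 at 18 h, 24 to 70 at 48 h, 40 to 159 at 72 h, 56 to 660 at any time, 332 to 1019 for late against early times and 4 to 52 neighbourhoods. It gave 0 to 2 for DHT in LNCaP, 148 to 301 in BicR and 0 to 1 by line, 0 to 1 for bicalutamide in LNCaP, 0 to 69 in BicR, 0 to 926 on DHT in BicR, and 363 to 1091 between the lines. A lone library was assumed to vary like the others. Of 258 values of 24 named sites, 207 kept their side of the threshold and 51 lost it, 40 of them with 1 library left out. Of all these values 0 turned direction. The 24 were at most the 2 largest rises and 2 largest falls of each comparison. Printed sites outside the 24 were not followed, so whether they hold without 1 library is not known. Sums per gene and gene lists were not run, nor a pseudocount in the tests, which used counts. With prior counts of 0.5 and 8 the R1881 and DHT correlation at 6 h was 0.323 and 0.321, and the DHT median of the rising set at 24 h in LNCaP was 0.805 and 0.726. The replicate correlation at 6 h was 0.534 and 0.694, at 18 h 0.56 and 0.703, and deviations of same-numbered libraries correlated at 0.113 and 0.144 at the least. Depth limits the time course, where 3 tags reach 19.45 RPM in its shallowest library.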

Other observations

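The test of rises along chromosomes, the chromosome 6 region and the 24 h against 6 h comparisons were chosen only after the results were seen. Levels also differed between 24 h and 6 h over all treatments. In LNCaP 13 sites were higher and 104 lower at 24 h, and in BicR, without the 3 libraries that hold tags at near-empty sites, 221 and 276. Without those libraries 0 sites passed in LNCaP, and with all libraries 1507 and 1368 passed in BicR. Of the lower sites 65 were shared by the LNCaP list from all libraries and the BicR list without the 3. Independent lists would share 2.16. With the 3 libraries left out of both lines the LNCaP list is empty, so this overlap does not hold for lines treated alike. Between 26 and 28 Mb of chromosome 6, a region picked for its falls, 11 of 55 sites fell in LNCaP and 18 of 49 in BicR. Position 27835365 on the minus strand fell from 176 ± 20.5 to 74.6 ± 20.5 RPM in LNCaP (log2 -1.27, SE 0.185, adjusted p = 0.0238; n = 4 each) and from 432 ± 41.8 (n = 3) to 137 ± 78.3 RPM (n = 4) in BicR (log2 -1.72, SE 0.231, adjusted p = 0.0272).

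A hypothesis was that divergent start sites, with the peak on the minus strand up to 1000 bp before that of the next site on the plus strand, change together at 48 h of R1881. Across 1701 such pairs the log2 changes correlated at r = 0.353 (Spearman's rho 0.227), and at most at 0.112 after re-pairing. The one-sided permutation p was 1e-05, the smallest possible. Pairs are not independent replicates, since all changes come from the same libraries. A bias that neighbouring sites share in those libraries could give a like correlation. In 30 pairs with a rising site, 25 partners had a log2 change above 0, with a median of 1.18 against 3.14 for the rising members, and 1 such pair held rises on both strands.

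Another hypothesis was that sites that rise have wider clusters than sites of like level. Their median width was 218 bp against 160 bp in matched lists, with a one-sided permutation p of 1e-05, the smallest possible. Falling sites had a median of 192 bp and no matched lists. The lists were matched on the mean log2 level over the 14 libraries, not on summed tags. Rising sites may hold more tags than their matches, and whether this accounts for their width was not tested.

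A further hypothesis was that sites that rise at 48 h lie near each other. Of 207 neighbourhoods with a rising site, 40 had another within 100 kb, against a mean of 11.4 and a highest of 36 in 10000 matched lists, with a one-sided permutation p of 1e-04, the smallest possible. Neighbourhoods joined sites of the same strand within 10000 bp only. Opposite-strand sites of the same locus, or same-strand sites slightly farther apart, thus counted as near each other. Part of the excess may come from such sites, and the test was not run without them. Examples are 5 sites from 36621691 to 36851539 on chromosome 1 and 3 sites from 51308026 to 51376761 on chromosome 19. In the first, 36690204 to 36690725 on the plus strand overlaps 36690342 to 36690443 on the minus strand.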
